A study of Mus musculus with 20 samples.

How the data were processed

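Transcript levels were measured on 20 two-colour spotted arrays in mouse fibroblasts with the heat shock factor 1 gene (HSF1 +/+, called WT here) and without it (HSF1 -/-, called KO here). Per the labels, the Cy5 channel of each array held the sample, and the Cy3 channel held a common pool of mRNA from fibroblasts heated for 1 h and from unheated ones. The deposited values are log2 ratios of sample over pool, 1 per probe and array. The base is not stated. The largest absolute value, 10.2, exceeds 4.82, the largest log10 ratio that 16-bit signals allow, so base 10 was excluded. Natural logarithms were not excluded, and folds given here would then be too small. How the authors corrected for background, filtered spots and normalized within arrays is not given in the sources used here. Spot intensities were not used here, so signal over background was not examined.

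The table held 42624 probes, of which 3.28% of values were missing and 32290 probes had a value on all 20 arrays. Arrays held 39037 to 42220 values each, with medians of -0.53 to -0.18, and pairs of arrays correlated across probes with r of 0.423 to 0.805. The number of arrays limits the precision. Probes were named by the platform table: 21701 probes listed 1 gene (10843 genes), 1124 listed several and 19799 listed none. Gene identifiers of 21650 probes were found in the mouse reference annotation, which changed 0 symbols. Probes with several genes or none were left out of the gene tests.

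Each array was centred on its median. A probe entered with at least 2 values in each of the 6 groups, which left 40453 probes, 20881 of them with 1 gene. The value of a gene was the mean of its probes, each taken relative to its own mean over the arrays. This gave 10625 genes, 5182 with 1 probe and 5443 with several. Near-identical genes, such as Hspa1a and Hspa1b, Mt1 and Mt2 or Tuba1b and Tuba1c, can bind each other's probes, so their values are not independent.

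The arrays fell into 6 groups: WT and KO at 0 h (n = 3 each), early (0.5, 1 and 2 h, n = 3 each) and late (3, 4, 6 and 8 h, n = 4 each). Only 0 h was repeated, so the arrays of a window are not replicates and their spread includes change over time. The labels do not say whether the 0 h arrays came from separate cultures, so p-values measure the spread between these arrays. Genotype cannot be separated from other differences between the cell lines. With limma, 1 linear model per gene was fitted to all 20 arrays (lmFit, eBayes, prior degrees of freedom 3.36). It gave 7 contrasts: KO minus WT at 0 h, early minus 0 h and late minus 0 h in each genotype, and WT minus KO in the early and in the late response. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a contrast and a threshold of 0.05 on the adjusted p. The error beside a log2 difference is the SE of the moderated fit.

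The groups, contrasts, gene lists and the rule for naming genes were fixed before the data were examined. The 20 functional lists were cytosolic chaperones and co-chaperones, mitochondrial chaperones and proteases, CCT chaperonin and prefoldin, ER chaperones and unfolded protein response, immediate early genes, proteasome subunits, ubiquitin and p97 pathway, antioxidant and metal response, p53 targets, mitosis, DNA replication, ribosomal proteins, ribosome biogenesis, cholesterol synthesis, glycolysis, mitochondrial respiratory chain, extracellular matrix, actin cytoskeleton, interferon and inflammatory response, and core histones. The 6 cell type lists were macrophage, epithelial, endothelial, muscle, adipocyte and neural markers. They hold 721 genes, 584 of them on the array. Each list with at least 5 measured genes was tested per contrast with camera (limma), which compares a list with all other genes. It was run at a preset correlation between genes of 0.01 on the 9459 genes with a value on every array, with adjustment over the 26 lists. List medians and counts use all tested genes. For core histones and for neural markers camera thus rests on 4 of the 5 measured genes. Camera was repeated with an estimated correlation, and with that setting 2 of the 55 list calls were kept: ribosome biogenesis at 0 h and cytosolic chaperones in the late response.

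The rule named Hsf1 and Hsf2 first. It then took the 10 largest rises and 10 largest falls past the threshold whose arrays all lay on one side of the compared group (no such condition for the response contrasts), and up to 4 genes of smallest p per list. Genes printed were drawn mainly from those that stayed past the threshold with any single array left out. Other genes are printed beside counts of 5 or fewer, or as examples of a list, and were chosen after their values were seen.

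The model was tested on simulated data, with noise drawn independently for each gene from its residual SD and 50 genes shifted at each of several sizes. At a log2 shift of 1 it recovered 48% of shifted genes at 0 h, 66% in WT early, 68% in WT late, 54% in KO early, 60% in KO late, 12% in the early response and 22% in the late response. At a shift of 2 it recovered 76% to 90%. Each shift was equal on all arrays of a window, so recovery of changes that build up within a window was not simulated. Per contrast, 3 to 12 genes that were not shifted were called. A list of 30 genes shifted by 0.5 was called in every contrast, and 0 of 25 unshifted lists were. As the simulated genes varied independently, this does not test false list calls where the genes of a list vary together. The estimated correlation between ribosomal protein genes, for example, was 0.65.

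Alternatives fixed in advance changed 1 choice at a time, except that blocking by replicate number also left only the 0 h arrays in the fit. They were centring, quantile normalization, scaling of each array to 1 median absolute deviation, 2 other filters on missing values, 1 probe per gene, tests of every probe, array weights, robust moderation, only the contrasted arrays, blocking by replicate number or by time, other list tests, and leaving out each array in turn. Chosen after seeing the data were the early window without both 0.5 h arrays, the late window without the KO arrays of 6 and 8 h, and list tests under the 3 scalings. Probes without a listed gene were examined only for probes that rose late in both genotypes. Tools were R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.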

Results

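Transcript levels were measured in mouse fibroblasts with heat shock factor 1 (HSF1 +/+, WT) and without it (HSF1 -/-, KO). HSF1 is the transcription factor that switches on chaperone genes when proteins unfold in the heat. Each genotype was measured on 3 arrays before heat shock (0 h) and on 1 array at each of 0.5, 1, 2, 3, 4, 6 and 8 h. Times were joined into an early window (0.5, 1 and 2 h, n = 3 per genotype) and a late window (3, 4, 6 and 8 h, n = 4 per genotype). Values are log ratios of each sample to a common reference pool, treated as log2, with 39037 to 42220 values per array, and the number of arrays limits their precision. Whether the cells stayed in the heat or recovered before harvest is not given in the sources used here.

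The targeted gene, Hsf1, and its relative Hsf2 had 0 probes listed with a single gene, so their transcripts were not analysed here. The genotypes differed in known targets of HSF1 after heat shock. Hspa1a, a stress-inducible chaperone of the HSP70 family, rose in WT cells by a log2 of 5.83 ± 0.75 (SE, 57-fold) in the late window (n = 4 against 3, limma adjusted p = 0.00184). In KO cells its late value was -0.01 (adjusted p = 0.999), with single arrays from -0.24 to 0.21. The difference between these responses was 5.84 ± 1.06 (adjusted p = 0.0438). With any 1 of the 14 contrasted arrays left out this call was lost (adjusted p from 0.0644 to 0.129), while the difference stayed between 5.65 and 6.11. It was also lost without centring (5.83, adjusted p = 0.0609), with 1 probe per gene (0.0569), with time as a block (0.0533) and without the KO arrays of 6 and 8 h, chosen after seeing the data (0.267).

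The first comparison asked how unstressed KO cells differed from unstressed WT cells. Some genes of the matrix around cells were higher in KO cells and some were lower (5 and 4 of 37 listed), and the list as a whole did not pass (median -0.11, camera adjusted p = 0.684). Postn, a matrix protein of wound repair, was higher by a log2 of 3.40 ± 0.22 (10.5-fold, n = 3 against 3, adjusted p = 1.42e-07), and Eln, which encodes elastin, by 2.31 ± 0.23 (adjusted p = 2.25e-05). The collagens Col6a1 (1.33 ± 0.19) and Col6a2 (1.89 ± 0.24) and the chemokine Cxcl12 (2.02 ± 0.21) were also higher. Lower in KO cells were Xist, the RNA that coats the inactive X chromosome (-3.31 ± 0.23, adjusted p = 2.52e-07), the collagen Col8a1 (-2.13 ± 0.20), the Wnt-related secreted protein Dkk3 (-2.42 ± 0.26) and the smooth muscle protein Cnn1 (-1.45 ± 0.25). For each of these genes the 3 KO values lay on one side of the 3 WT values, an outcome that chance gives for 10% of genes. It was also a condition for naming the largest rises and falls, so it is not further support for them. The mean for Xist rests on 4 probes that ranged from -5.17 to 0.49.

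Ribosomal protein transcripts were lower in KO cells as a group. Their median difference was -1.02, with 56 of 62 genes lower over all genes and 62 of 62 when adjusted over the list alone (camera adjusted p = 8.64e-55, adjusted p = 0.0866 with an estimated correlation). Rps14 (-1.38 ± 0.17, adjusted p = 0.000117) and Rpl36 (-1.25 ± 0.16) are examples. Ribosome biogenesis genes were lower in the same comparison, with a median of -0.43 and 8 of 25 lower (10 adjusted over the list alone, camera adjusted p = 2.42e-06, adjusted p = 0.0267 with an estimated correlation). Among them were the nucleolar proteins Gnl3 (-1.08 ± 0.17) and Npm1 (-1.03 ± 0.22). Npm1 no longer passed under quantile normalization or under scaling of array width.

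Further groups of abundant transcripts were lower in KO cells. These were the CCT chaperonin and prefoldin, which fold actin and tubulin (median -0.61, 5 of 13 lower, 9 adjusted over the list alone), proteasome subunits (-0.50, 7 of 33, 14 adjusted over the list alone) and the mitochondrial respiratory chain (-0.39, 10 of 59, 18 adjusted over the list alone). Camera adjusted p values were 1.57e-07, 1.15e-07 and 2.01e-10 for these 3 lists, and each call was lost: adjusted p = 0.106, 0.275 and 0.339 with an estimated correlation. Examples are the chaperonin subunit Cct6a (-1.13 ± 0.25), the proteasome subunit Psmd8 (-0.95 ± 0.20) and cytochrome c, Cycs (-1.02 ± 0.18). Actin cytoskeleton genes (-0.44, 6 of 28 lower, 8 adjusted over the list alone, adjusted p = 9.28e-07) and glycolysis genes (-0.33, 5 of 17, 6 adjusted over the list alone, adjusted p = 0.000161) were lower too, with adjusted p = 0.339 and 0.106 with an estimated correlation. The non-muscle myosin Myh9 (-0.72 ± 0.16) and the lactate dehydrogenase Ldha (-1.11 ± 0.24) belong to them, and Myh9 did not pass under quantile normalization or scaling of array width. The glycolysis median was -0.18 without KO 0 h replicate 3 and -0.50 without WT 0 h replicate 3.

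Chaperones and stress defence genes were lower by smaller amounts before heat shock. Cytosolic chaperones had a median of -0.22 (4 of 35 lower, 6 adjusted over the list alone, camera adjusted p = 0.0137). For antioxidant and metal response genes the median was -0.26 (3 of 22 lower and 1 higher, 7 and 1 adjusted over the list alone, adjusted p = 0.00436), with thioredoxin, Txn1, lower by -1.22 ± 0.19. ER chaperones had a median of -0.20 (1 of 25 lower, 1 adjusted over the list alone, adjusted p = 0.0215), which was -0.33 without KO 0 h replicate 1. Their 1 lower gene was Manf, a secreted protein of the ER stress response (-1.10 ± 0.18). All 3 calls had adjusted p = 0.339 with an estimated correlation, and the antioxidant and ER calls were lost under quantile normalization (adjusted p = 0.0748 and 0.375). Core histones (median -0.57, 2 of 5 lower, 2 adjusted over the list alone, adjusted p = 0.0202) lost their call without KO 0 h replicate 2 (0.0501), and had adjusted p = 0.275 with an estimated correlation. Mitochondrial chaperones (median -0.21, 2 of 13 lower, 4 adjusted over the list alone, adjusted p = 0.0275) lost theirs without WT 0 h replicate 1 (0.0653), WT 0 h replicate 2 (0.0543) or KO 0 h replicate 2 (0.0778), and had adjusted p = 0.106 with an estimated correlation.

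The other lists did not pass between unstressed genotypes, which does not show that their genes were equal. Extracellular matrix genes had a mean of 0.15, opposite in sign to their median, with 8 of 37 higher and 8 lower adjusted over the list alone. Medians and adjusted p were -0.13 and 0.207 for mitosis, -0.18 and 0.207 for immediate early genes, -0.11 and 0.426 for the ubiquitin and p97 pathway, 0.20 and 0.426 for the interferon and inflammatory response, and -0.12 and 0.47 for cholesterol synthesis. For DNA replication (0.08, 0.88) and p53 targets (0.23, 0.967) the median was positive while the test pointed down. Markers of other cell types did not pass either, with medians and adjusted p of 0.17 and 0.431 for adipocyte, -0.10 and 0.47 for muscle, 0.06 and 0.482 for macrophage, -0.16 and 0.643 for neural, -0.04 and 0.88 for endothelial and 0.09 and 0.967 for epithelial markers. The neural mean was positive (0.05), and the macrophage and epithelial tests pointed down.

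In all, 705 of 10625 genes passed at 0 h, 323 higher and 382 lower in KO cells. The count fell to 109 with only the 6 contrasted arrays in the fit, to 423 without KO 0 h replicate 3 and to 458 without KO 0 h replicate 2, and Cct6a did not pass with 1 probe per gene. The genes lower in KO cells no longer outnumbered the higher ones without centring (286 and 408, with a median of all genes of 0.16), after quantile normalization (232 and 376) or after scaling of array width (225 and 295). Nor did they without WT 0 h replicate 2 (365 and 365), KO 0 h replicate 2 (216 and 242) or KO 0 h replicate 3 (209 and 214).

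The next comparison asked what changed in WT cells in the first 2 h. A single gene rose and 3 fell, out of 1202 with an unadjusted p under 0.05. Another split of the same arrays gave 5 genes, so this count does not exceed what other splits gave. The gene that rose was Dnajb1, a cofactor of HSP70 chaperones (1.78 ± 0.26, n = 3 against 3, adjusted p = 0.0302), with values of 1.16, 2.06 and 2.14 at 0.5, 1 and 2 h. Lower were the homeobox gene Pknox2 (-2.00 ± 0.33, adjusted p = 0.0393, 1 probe), the antibody receptor gene Fcgr1 (-1.59 ± 0.26, 0.0383) and the palmitoyltransferase gene Zdhhc16 (-1.47 ± 0.24, 0.0383). Hspa1a did not pass over the window (3.64 ± 0.80, adjusted p = 0.123): it stood at 0.58 at 0.5 h, 4.55 at 1 h and 5.80 at 2 h. In the fit without both 0.5 h arrays, chosen after seeing the data, it passed (5.17, adjusted p = 6.02e-06), as did Hspa1b (4.50, adjusted p = 6.77e-05). Each of the 4 calls was lost without the WT 1 h array or without the WT 2 h array (adjusted p = 0.119 for all 4 at 2 h, 0.0642 to 0.0943 at 1 h). Dnajb1 was also lost without WT 0 h replicate 1 (0.106) or 2 (0.0822), Fcgr1 without replicate 1 (0.0597) or 2 (0.0566), Zdhhc16 without replicate 1 (0.0625) and Pknox2 without the WT 0.5 h array (0.0675). Pknox2 was not tested without WT 0 h replicate 1 or 3, as its probe gave values on these 2 of the 3 arrays. The number of genes was 7, 18 and 8 without WT 0 h replicates 1, 2 and 3, and 11 without the WT 0.5 h array.

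Ribosomal protein transcripts fell in the early WT window, with a median of -0.41 (0 of 62 past the threshold over all genes, 10 lower adjusted over the list alone, camera adjusted p = 2.33e-20, adjusted p = 0.713 with an estimated correlation). Their medians were -0.19, -0.55 and -0.52 at 0.5, 1 and 2 h. The mitochondrial respiratory chain fell with a median of -0.27 (0 of 59 over all genes, 2 lower adjusted over the list alone, adjusted p = 4.69e-09, adjusted p = 0.758 with an estimated correlation). Cytosolic chaperones rose, with a median of 0.19 and a mean of 0.49 (1 of 35 over all genes, 3 higher adjusted over the list alone, adjusted p = 0.0014, adjusted p = 0.713 with an estimated correlation), a call lost without the WT 2 h array (0.0543).

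Falls in the early WT window were called for 5 more lists, none of which kept its call under quantile normalization or scaling of array width. Proteasome subunits had a median of -0.19 (0 of 33 over all genes, 1 lower adjusted over the list alone, adjusted p = 0.00479), which was lost without the WT 1 h (0.0819) or 2 h (0.0543) array and was -0.30 without the WT 0.5 h array. Actin cytoskeleton genes (-0.18, 0 of 28 by either count, adjusted p = 0.0145) lost the call without WT 0 h replicates 1 (0.051) or 3 (0.0548), or the WT 1 h (0.432) or 2 h (0.552) array. Their median was -0.11 and -0.10 without those last arrays, -0.39 without the WT 0.5 h array and 0.01 without centring, where the median of all genes was 0.19. Antioxidant genes (-0.26, 0 of 22 by either count, adjusted p = 0.037) lost it without WT 0 h replicates 1 (0.0645) or 3 (0.385, median -0.15), or the WT 1 h (0.432, median -0.16) or 2 h (0.0543) array. Glycolysis genes (-0.26, 0 of 17 by either count, adjusted p = 0.0394) lost it without WT 0 h replicates 1 (0.589, median -0.04) or 2 (0.204), or the WT 1 h (0.168) or 2 h (0.0693) array. Core histones (-0.34, 0 of 5 by either count, adjusted p = 0.037) lost it without WT 0 h replicates 1 (0.125) or 3 (0.132), or the WT array of 1 h (0.215), 2 h (0.262), 4 h (0.0583) or 8 h (0.0526). With an estimated correlation the adjusted p was 0.843 for proteasome, 0.867 for actin, 0.843 for antioxidant, 0.758 for glycolysis and 0.713 for histone genes. Immediate early genes had a median of 0.28 (1 higher adjusted over the list alone) and did not pass (adjusted p = 0.161).

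WT cells were compared with their unstressed state again at 3 to 8 h. Chaperone genes rose in these cells. Of 35 cytosolic chaperones and co-chaperones 15 rose and 0 fell (15 and 1 adjusted over the list alone), with a median of 0.39 and a mean of 0.87 (camera adjusted p = 8.14e-07, adjusted p = 0.24 with an estimated correlation). Hspa1b, almost identical to Hspa1a, rose by 5.28 ± 0.74 (adjusted p = 0.00233), and each of these 2 genes rests on 1 probe, which for Hspa1b gave values on 2 of the 3 WT 0 h arrays. Dnajb1 rose by 2.11 ± 0.25 (adjusted p = 0.00121, 3 probes), Hsph1, a nucleotide exchange factor of HSP70, by 2.32 ± 0.37 (4 probes) and the stress-inducible HSP90 gene Hsp90aa1 by 1.36 ± 0.19 (11 probes, from -0.02 to 1.65). All 4 late arrays lay above the 0 h mean for each of these genes. The mitochondrial chaperonin partners Hspd1 (0.84 ± 0.18) and Hspe1 (1.09 ± 0.22) rose, while the mitochondrial chaperone list as a whole did not pass (median -0.05, mean 0.19, 3 of 13 higher by either count, adjusted p = 0.58).

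**Figure D1:**
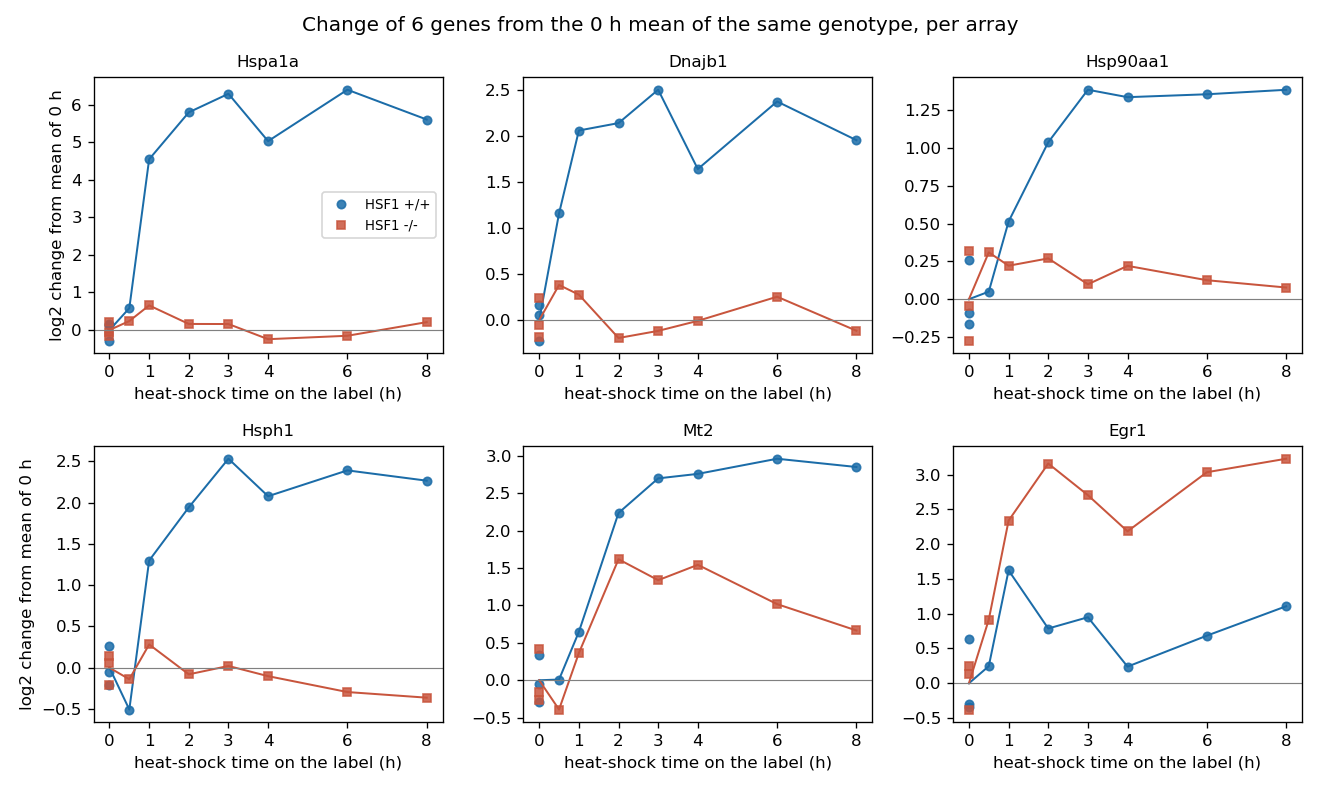
Change from the genotype's own 0 h mean (log2 ratio, vertical axis) on each array against the labelled heat-shock hours (horizontal axis) for 6 genes. WT is in blue circles and KO in red squares. Points are single arrays, and lines start from the 0 h mean. In WT cells Hspa1a reached 4.55 at 1 h and 6.29 at 3 h, and in KO cells it stayed between -0.24 and 0.66.

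Some single genes of metal binding and stress rose in late WT cells. The metallothioneins Mt2 (2.82 ± 0.45, adjusted p = 0.00269) and Mt1 (1.47 ± 0.25), the stress transcription factor Atf3 (1.73 ± 0.30), Zfand2a, a partner of the proteasome under stress (1.29 ± 0.25), and the interferon signalling factor Irf9 (1.35 ± 0.27) are examples. The lists that hold them did not pass: antioxidant and metal response (median -0.31, 18 of 22 genes below 0, 2 of 22 higher and 2 lower, 2 and 6 adjusted over the list alone, adjusted p = 0.0712), immediate early genes (0.17, 4 of 26 higher and 2 lower, 7 and 3 adjusted over the list alone, adjusted p = 0.0712), the ubiquitin and p97 pathway (-0.17, adjusted p = 0.599) and the interferon and inflammatory response (0.12, adjusted p = 0.732).

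Cell division genes and histone genes fell in late WT cells. Mitosis genes had a median of -0.32, with 7 of 32 lower and 0 higher (9 and 1 adjusted over the list alone, camera adjusted p = 4.63e-05, adjusted p = 0.24 with an estimated correlation). Cks2, a subunit of mitotic kinases, fell by 1.05 ± 0.19 on the log2 scale and the kinesin Kif22 by 1.32 ± 0.25. Core histones had a median of -0.61 (3 of 5 lower by either count, adjusted p = 0.00113, adjusted p = 0.24 with an estimated correlation), or -1.05 without WT 0 h replicate 3. The variants H2ax (-1.46 ± 0.24) and H3f3b (-1.14 ± 0.19) were among them. DNA replication genes (-0.20, 1 of 34 lower by either count, adjusted p = 0.0448, adjusted p = 0.644 with an estimated correlation) included the replication inhibitor Gmnn (-1.01 ± 0.18). Their call was lost without any 1 of 9 arrays: WT 0 h replicates 1 (0.132), 2 (0.285) and 3 (0.0731), WT 0.5 h (0.0581), 1 h (0.0561), 4 h (0.104), 6 h (0.0624) and 8 h (0.0599), and KO 1 h (0.0576). The p53 target Ccng1 fell by 0.81 ± 0.14, while p53 targets as a list did not pass (median -0.00, 1 higher and 1 lower, adjusted p = 0.713).

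Structural and metabolic genes fell as well. Actin cytoskeleton genes had a median of -0.42 (5 of 28 lower, 7 adjusted over the list alone, adjusted p = 1.1e-05), proteasome subunits -0.43 (2 of 33, 10 adjusted over the list alone, adjusted p = 1.47e-05) and the respiratory chain -0.31 (4 of 59, 5 adjusted over the list alone, adjusted p = 4.63e-05). With an estimated correlation these had adjusted p = 0.644, 0.644 and 0.659, and scaling of array width ended the respiratory call (0.0746). Psmb1, a proteasome subunit, fell by 0.84 ± 0.18 and Ndufa9, of respiratory complex I, by 0.68 ± 0.14. Ribosomal proteins had a median of -0.24 (0 of 62 by either count, adjusted p = 0.000222, adjusted p = 0.659 with an estimated correlation), a call lost without WT 0 h replicate 3 (0.0731) or the WT 4 h array (0.0945, median -0.13), and the median turned to 0.03 under scaling of array width. Glycolysis genes (-0.25, 2 of 17 lower, 3 adjusted over the list alone, adjusted p = 0.00859, adjusted p = 0.448 with an estimated correlation) lost the call without WT 0 h replicate 1 (0.0664) and under scaling of array width (0.0746). Extracellular matrix genes (-0.23, 1 of 37 lower by either count, adjusted p = 0.0448, adjusted p = 0.659 with an estimated correlation) lost it without WT 0 h replicates 1 (0.108) or 3 (0.156), or the WT array of 0.5 h (0.0575), 1 h (0.0561), 2 h (0.0629), 4 h (0.165, median -0.14) or 8 h (0.115). The matrix protein gene Thbs1 fell by 0.85 ± 0.17. CCT chaperonin and prefoldin (-0.31, adjusted p = 0.121), cholesterol synthesis (-0.24, 0.172), ribosome biogenesis (-0.04, 0.905) and ER chaperones (-0.01, 0.905) did not pass, nor did the 6 cell type lists (adjusted p from 0.58 to 0.951), and ribosome biogenesis and ER chaperones had positive means (0.06 and 0.02).

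**Figure D2:**
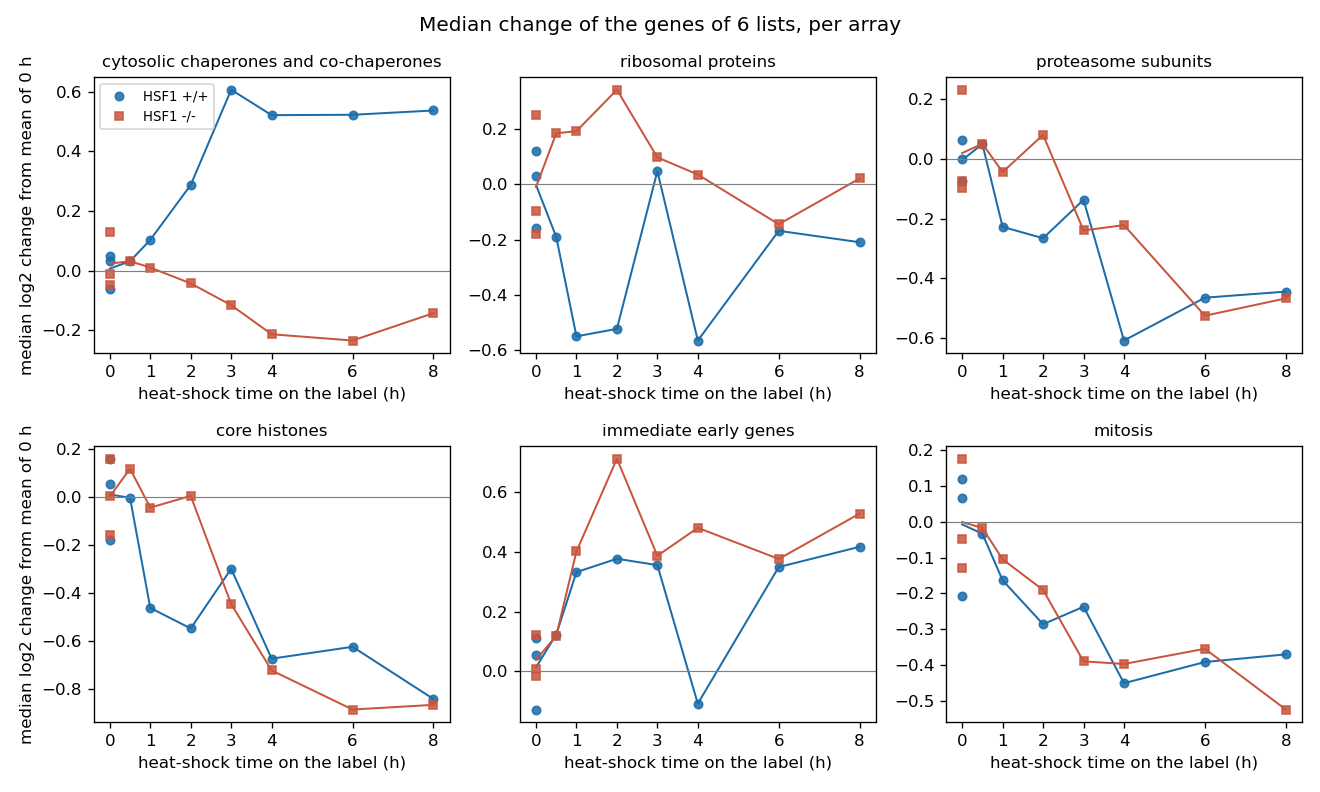
Median change of 6 gene lists from the genotype's own 0 h mean (log2 ratio, vertical axis) on each array against the labelled heat-shock hours (horizontal axis). WT is in blue circles and KO in red squares. Points are medians over the genes of a list on 1 array. Cytosolic chaperones reached 0.61 in WT at 3 h and stood between -0.24 and -0.12 in KO from 3 to 8 h.

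Altogether 772 genes passed in late WT cells, 382 higher and 390 lower. The number was 385 without the WT 8 h array and 437 without the WT 6 h array, 164 with only the contrasted arrays in the fit, and higher genes outnumbered lower ones under the 3 other scalings (60.2% higher without centring). Some of the largest rises, such as those of Kif28 (3.07 ± 0.51) and Efhb (3.05 ± 0.56), rest on 1 probe, and they rose in KO cells too (3.85 ± 0.51 and 3.56 ± 0.56). With 1 probe per gene Hspe1, Gmnn and Ccng1 did not pass. Among probes that rose late in both genotypes, other probes of the same genes had a median change of 0.03, against 1.76 for the risers themselves.

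Early changes in KO cells were tested in the same way. With limma 0 genes passed, and 793 had an unadjusted p under 0.05. Without the KO 0.5 h array 6 genes passed, and 1 did without KO 0 h replicate 3 or without the KO 2 h array. Egr1, a transcription factor induced within minutes by many stimuli, had the value 2.14 ± 0.47 (n = 3 against 3, adjusted p = 0.315), with 0.91, 2.34 and 3.16 at 0.5, 1 and 2 h, and it passed without both 0.5 h arrays, an alternative chosen after seeing the data (2.75, adjusted p = 0.018). Immediate early genes rose as a list, with a median of 0.42 (0 over all genes, 1 higher adjusted over the list alone, camera adjusted p = 7.32e-07, adjusted p = 0.266 with an estimated correlation), or 0.27 without the KO 2 h array. Ribosomal proteins rose with a median of 0.24 (0 of 62 by either count, adjusted p = 2.13e-13, adjusted p = 0.691 with an estimated correlation), or 0.37 without KO 0 h replicate 1. Cytosolic chaperones did not pass (median 0.00, mean -0.04, adjusted p = 0.613), and no other list did.

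In the late KO window immediate early genes were higher than before heat shock: of 26, 9 passed upwards and 1 downwards (11 and 2 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 0.000215, adjusted p = 0.232 with an estimated correlation). Egr1 rose by 2.79 ± 0.44 (6.91-fold, n = 4 against 3, adjusted p = 0.000909, 1 probe) and stayed between 2.18 and 3.23 on the 4 late arrays. Ccl2, a chemokine that attracts monocytes, rose by 1.75 ± 0.36. Ribosome biogenesis genes rose with a median of 0.13 (3 of 25 higher by either count, adjusted p = 0.00727, adjusted p = 0.232 with an estimated correlation), among them Polr1b, a subunit of RNA polymerase I (1.64 ± 0.25). Cytosolic chaperones did not pass (median -0.15, 4 of 35 lower by either count, adjusted p = 0.254). Dnajb1 (0.00, adjusted p = 0.997) and Hspa1b (-0.52, adjusted p = 0.681) did not pass, while Hspa5, the HSP70 of the ER, fell by 0.90 ± 0.19.

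Genes of DNA synthesis and mitosis fell in late KO cells. DNA replication genes had a median of -0.42 (6 of 34 lower, 10 adjusted over the list alone, adjusted p = 0.000934) and mitosis genes -0.47 (9 of 32 lower, 13 and 1 higher adjusted over the list alone, adjusted p = 0.000253), both with adjusted p = 0.232 with an estimated correlation. Rrm1, the large subunit of ribonucleotide reductase, fell by 2.19 ± 0.23 (adjusted p = 0.000274) and moved from -0.87 at 0.5 h to -2.06 at 8 h. The replication inhibitor Gmnn fell by 0.99 ± 0.18, and the spindle checkpoint gene Mad2l1 by 1.26 ± 0.23, which did not pass with 1 probe per gene. Other large falls were those of Cxcl12 (-1.65 ± 0.20), its receptor gene Cxcr4 (-2.27 ± 0.43, or -1.32 without the KO arrays of 6 and 8 h, chosen after seeing the data), the redox regulator Txnip (-2.04 ± 0.24), the splicing factor Srsf5 (-1.98 ± 0.35) and the tubulin Tuba1b (-2.06 ± 0.32).

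Cytoskeletal and metabolic lists fell in late KO cells too. Their medians were -0.54 for actin cytoskeleton (9 of 28 lower, 16 adjusted over the list alone, adjusted p = 2.53e-06), -0.38 for the respiratory chain (12 of 59 lower and 2 higher, 14 and 2 adjusted over the list alone, 1.64e-05), -0.36 for proteasome subunits (2 of 33 by either count, 0.000461) and -0.52 for glycolysis (6 of 17, 10 adjusted over the list alone, 0.00123). CCT chaperonin and prefoldin (-0.42, 2 of 13 by either count, 0.00727), extracellular matrix (-0.36, 6 of 37, 7 adjusted over the list alone, 0.00162) and antioxidant genes (-0.33, 8 of 22 lower, 9 and 3 higher adjusted over the list alone, 0.00927) followed. Each had adjusted p = 0.404 with an estimated correlation, except the respiratory chain (0.413) and glycolysis (0.232), and the matrix call was lost under scaling of array width (0.172). Examples are Actb, a main actin of the cytoskeleton (-0.96 ± 0.22), Sdhc of respiratory complex II (-1.02 ± 0.17), Ldha (-1.15 ± 0.22), Cct3 (-1.02 ± 0.17) and Prdx1, which removes peroxides (-1.16 ± 0.19). Other lists did not pass: core histones (median -0.73, adjusted p = 0.0667), ER chaperones (-0.28, 0.0706), interferon response (0.23, 0.136), ubiquitin pathway (-0.18, 0.296), ribosomal proteins (0.00, 0.459), p53 targets (-0.05, 0.61), mitochondrial chaperones (-0.08, 0.685) and cholesterol synthesis (-0.13, 0.982). Cell type lists had adjusted p of 0.267 to 0.421.

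In total 1133 genes passed in late KO cells, 410 higher and 723 lower. Lower genes did not outnumber higher ones without KO 0 h replicate 1 (261 and 262), and did so by less without centring (463 and 419). Leaving out 1 array changed this most for KO 0 h replicate 1 (523), KO 8 h (694), KO 6 h (708) and KO 0 h replicate 3 (743). The KO arrays of 6 and 8 h correlated least with the KO 0 h arrays (mean r across genes 0.525 and 0.527). Without both of them, an alternative chosen after seeing the data, 220 genes passed, 216 of them among the 1133. Hspa5 (-0.54), Ldha (-1.01) and Actb (-0.90) were among those that no longer did, the last 2 at falls close to those given. Late calls overlapped between the genotypes: 197 genes rose in both (14.7 if independent), 177 fell in both (26.5 if independent) and 3 moved in opposite directions. For probes that rose in both, other probes of the same genes changed by 0.0163 of the riser's own value, against 0.593 for probes that fell in both, so the 197 are not all shown to be changes of the named transcripts.

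The response contrasts asked which changes differed between genotypes. In the early window limma called 0 genes, with 889 at an unadjusted p under 0.05, and the number was 5 without WT 0 h replicate 2, 3 without the WT 0.5 h array and 1 without the KO 0.5 h array. Dnajb1 had a difference of 1.63 ± 0.37 (adjusted p = 0.54) and Hspa1a of 3.29 (adjusted p = 0.581). In the fit without both 0.5 h arrays, chosen after seeing the data, 5 genes passed, among them Hspa1a (4.77, adjusted p = 0.00111), Hspa1b (5.03, 0.00111) and Dnajb1 (2.06, 0.048). Ribosomal proteins differed as a list, with a median of -0.66 and 62 of 62 genes below 0 (0 over all genes, 32 lower adjusted over the list alone, camera adjusted p = 1.21e-33). The same 0 h arrays gave the ribosomal difference between unstressed genotypes, so these results are not independent. The respiratory chain differed by a median of -0.36 (0 of 59 over all genes, adjusted p = 9.53e-10). Cytosolic chaperones had a median of 0.26 and a mean of 0.53 (0 over all genes, 2 higher adjusted over the list alone, adjusted p = 0.0359), a call lost without WT 0 h replicates 2 or 3, the WT 2 h array, KO 0 h replicate 1 or the KO arrays of 0.5 or 2 h (adjusted p from 0.0574 to 0.237). Their median was 0.16 without the WT 0.5 h array or KO 0 h replicate 1 and 0.12 without the WT 2 h array. Each of the 3 lists had adjusted p = 0.631 with an estimated correlation.

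In the late window 10 genes differed between the responses of WT and KO cells, 8 more positive and 2 more negative in WT, among 926 with an unadjusted p under 0.05. Chaperone genes made up 5 of them: Hspa1a, Hspa1b (5.80 ± 0.99, adjusted p = 0.0438), Dnajb1 (2.11 ± 0.35, 0.0402) and the small heat shock proteins Hspb8 (1.77 ± 0.29, 0.0402) and Cryab (1.64 ± 0.24, 0.036). In late KO cells Hspb8 and Cryab fell past the threshold, so their differences rest in part on a fall in KO. Both falls no longer passed without the KO arrays of 6 and 8 h (-0.65 and -0.49, adjusted p = 0.217 and 0.264). Rrm1 (1.75 ± 0.32, 0.0498), the secreted protein gene Islr (1.56 ± 0.28, 0.0438) and Lipa, a lysosomal lipase (1.38 ± 0.25, 0.0438), were also more positive. More negative were Zdhhc16 (-1.82 ± 0.32, 0.0438), whose 2 probes gave -3.24 and -0.36, and Fbxo5, an inhibitor of the mitotic ubiquitin ligase (-1.24 ± 0.22, 0.0438). All 10 calls were lost without WT 0 h replicate 3, the WT 3 h or 6 h array, KO 0 h replicate 1 or the KO 4 h, 6 h or 8 h array. Another gene passed without KO 4 h, and 1 to 6 genes passed without any other WT or KO array of 0 h or the late window (1 without KO 3 h, 2 without KO 0 h replicate 2, 3 without WT 4 h, 4 without KO 0 h replicate 3, 5 without WT 8 h, and 6 without WT 0 h replicate 1 or 2). With limma 0 genes passed without centring, with time as a block or without the KO arrays of 6 and 8 h, and with 1 probe per gene only Zdhhc16 did (-3.24), while Rrm1 was 0.57. The 5 chaperone differences stayed within 1.5 times those given in each of these fits. Without the KO arrays of 6 and 8 h, an alternative chosen after seeing the data, they were 5.88 for Hspa1a, 5.86 for Hspa1b, 2.18 for Dnajb1, 1.75 for Hspb8 and 1.49 for Cryab.

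Cytosolic chaperones differed as a group in the late response. Of 35 genes 29 lay above 0, with a median of 0.71 and a mean of 1.02 (5 higher over all genes, 12 higher adjusted over the list alone). The camera adjusted p was 7.5e-13, and adjusted p = 0.0318 with an estimated correlation, and the median lay between 0.61 and 0.84 with any single array left out. Ribosomal proteins (-0.22, 0 of 62 over all genes, adjusted p = 2.22e-06, adjusted p = 0.757 with an estimated correlation) and ribosome biogenesis genes (-0.29, 0 of 25 over all genes, adjusted p = 0.0118, adjusted p = 0.252 with an estimated correlation) were more negative in WT. The ribosomal median was -0.11 without the WT 4 h array and -0.35 without KO 0 h replicate 1. Immediate early genes (-0.25, adjusted p = 0.0689), ER chaperones (0.37, 0.0689), DNA replication (0.15, 0.22) and mitochondrial chaperones (0.22, 0.248) did not pass, nor did any other list (adjusted p from 0.248 to 0.988). For macrophage markers (median 0.10), endothelial markers (0.27) and mitosis (0.08) the test pointed down. The single-gene differences for Egr1 (-2.04 ± 0.62, adjusted p = 0.379), Mt2 (1.68, 0.484) and Hsp90aa1 (1.23, 0.126) did not pass either, so that their responses were not shown to differ.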

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

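Of the tests of explanations below, all but those on a second spot of the same accession and on the width of log ratios for ribosomal proteins were chosen only after the result was seen, as were the list tests under other scalings. The contrasts, the other list tests and the left-out arrays were fixed in advance.

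In the late response 10 genes differed between the genotypes by the test of the difference itself. The values, as WT minus KO on the log2 scale, were 5.84 for Hspa1a, 5.80 for Hspa1b, 2.11 for Dnajb1, 1.77 for Hspb8, 1.75 for Rrm1, 1.64 for Cryab, 1.56 for Islr, 1.38 for Lipa, -1.24 for Fbxo5 and -1.82 for Zdhhc16. Each kept its sign in every fit with 1 array left out that tested it. Hspa1b was not tested without either of the 2 WT 0 h arrays on which its probe gave values. Of the arrays left out singly, 7 to 14 ended each call (the report gives the counts without each). The Rrm1 difference was 0.57 with 1 probe per gene.

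Gene lists differed between the responses as well. In the late response the medians were 0.71 for cytosolic chaperones, -0.22 for ribosomal proteins and -0.29 for ribosome biogenesis genes. In the early response they were -0.66 for ribosomal proteins, -0.36 for the respiratory chain and 0.26 for cytosolic chaperones. The 0 h arrays behind the lower ribosomal level of unstressed KO cells enter both ribosomal medians. With an estimated correlation only the late chaperone call was kept (adjusted p = 0.0318): the others had 0.757 for ribosomal proteins and 0.252 for ribosome biogenesis in the late response, and 0.631 for each of the 3 early lists. A further 6 lists passed there with 0 genes past the threshold over all genes or over the list alone, and each had adjusted p = 0.631 with an estimated correlation. Their medians and camera adjusted p were -0.22 and 0.00632 for actin cytoskeleton, -0.20 and 0.0111 for proteasome subunits, -0.39 and 0.0399 for core histones, -0.28 and 0.0413 for CCT chaperonin and prefoldin, -0.14 and 0.0438 for antioxidant genes, and -0.16 and 0.0491 for immediate early genes. None of these 6 kept its call under quantile normalization or under scaling of array width. Without centring, where the median of all genes was 0.31, the actin (0.04), proteasome (0.06), antioxidant (0.12) and immediate early (0.11) medians turned positive.

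Single arrays ended each of these 6 early calls. For actin and proteasome they were WT 1 h, WT 2 h and KO 0 h replicate 2 (adjusted p up to 0.135 and 0.0855). Actin stood at -0.53 without WT 0.5 h, -0.09 without WT 2 h and -0.11 without KO 0 h replicate 2, and proteasome at -0.03 without WT 0 h replicate 2, -0.13 without KO 0 h replicate 2 and -0.07 without KO 0 h replicate 3. Core histones lost the call without WT 0 h replicates 1 or 3, WT 1 h or 2 h, KO 0 h replicate 2, or KO 0.5 h or 2 h (up to 0.14). The chaperonin list lost it without WT 0 h replicates 2 or 3, WT 1 h or 2 h, KO 0 h replicates 2 or 3, or KO 0.5 h or 2 h (up to 0.312), with medians from -0.47 without WT 0.5 h to -0.10 without WT 1 h. Antioxidant genes lost it without any WT 0 h replicate, WT 1 h or 2 h, KO 0 h replicates 2 or 3, or KO 0.5 h or 2 h (up to 0.338), with medians from -0.24 without KO 1 h to -0.00 without WT 0 h replicate 3. Immediate early genes kept it only without WT 0 h replicates 1 or 3, WT 1 h, WT 2 h, KO 0.5 h or KO 3 h (up to 0.542 otherwise, without KO 2 h), with medians from -0.27 without WT 0 h replicate 3 to -0.08 without WT 0.5 h or KO 2 h.

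Probes outside the gene tests were examined too. Of 1060 probes that rose late in both genotypes, 821 (77.5%) list no gene, against 48.4% of all probes in the fit. On the early arrays, which were not in the contrasts that chose them, the median over all 1060 was -0.17, 0.68 and 0.91 at 0.5, 1 and 2 h in WT and 0.13, 0.66 and 0.99 in KO.

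Other probes of the genes of these risers moved little: over 165 risers with such a probe, its median change was 0.0163 of the riser's own, against 0.593 for 79 probes that fell late in both genotypes. That is consistent with risers that detect something other than the mature transcript of the named gene. Faulty single spots were tested with a second spot of the same accession, which gave 0.0316 over 10 risers, but the fallers gave 0.0974 over 9, so this test cannot separate them. A later test argues against faults that vary at random between arrays. The median riser rose by 0.89 from 0.5 to 2 h in the genotype with the smaller rise. A spot fault that changes with time would rise as well, so the test cannot decide on it. Narrower log ratios are argued against by late levels that lay further from the array median than the 0 h levels. The difference was a median of 1.25 (quartiles 1.01 and 1.86) in WT and 1.49 in KO. Shared repeat sequence, wrong clones or unspliced transcripts made in the heat stay open, as no sequences were examined.

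Ribosomal protein transcripts were lower in unstressed KO cells, and these explanations were weighed against a difference between the cell lines. A different width of log ratios between arrays is argued against by the median after scaling, -0.73, and a single aberrant array by the median nearest to 0 with 1 array left out, -0.93. A bias of bright spots and a real difference cannot be told apart: the lowest of 4 other lists of abundant transcripts had a median of -0.50, and no spot brightness was used here to set against it. A real difference between the lines stays open and untested, and it could not be assigned to genotype, which is confounded with the line.

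Late levels moved nearer to the reference in both genotypes, with a slope of change on 0 h level of -0.15 in WT and -0.28 in KO across genes, which are not independent replicates. In KO, ribosomal proteins changed by a median of 0.00, where the slope predicts -0.22, a ratio of -0.0185. This list cannot decide on a uniform narrowing of log ratios, as a rise of its own genes would offset one. The median absolute deviation on KO arrays was 0.758, 0.542 and 0.605 at 0 h. At 3, 4, 6 and 8 h it was 0.502, 0.574, 0.475 and 0.460. On WT arrays it was 0.744, 0.728 and 0.753 at 0 h, and 0.745, 0.549, 0.610 and 0.620 at those times. In WT the observed and predicted ribosomal changes were -0.24 and -0.28, so narrowing is not argued against by that list there either. Missing values on late arrays numbered 0.547 of those at 0 h in WT and 0.823 in KO. How spots were filtered is not given, so these counts cannot decide on a larger share of dim spots on late arrays. A shared response of both lines to heat, or to time in culture, may contribute and was not tested, as there are no unheated arrays at later times.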

How the results depend on the processing

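The early windows without 0.5 h, the late window without the KO arrays of 6 and 8 h and the list tests under other scalings were chosen after seeing the data, and the other alternatives were planned. Counts of genes past the threshold were within 1.5 times those reported except as follows, and unless a reason is given the cause was not tested. At 0 h (705) the count was 3234 with every probe tested, which also tests more items, 109 with only the contrasted arrays, which leaves fewer degrees of freedom, and 0 with the replicate number as a block on the 0 h arrays, where same-numbered arrays of the genotypes did not correlate as pairs (r of 0.010, -0.015 and -0.003). In early WT (4) it was 1 without centring, 2 after quantile normalization, with probes on all arrays or with 1 probe per gene, 0 after scaling of array width or with only the contrasted arrays, 8 with probes of at least 1 value per group, 10 with every probe, 9 with array weights and 10 without 0.5 h. In late WT (772) it was 462 after quantile normalization, 371 after scaling, 4270 with every probe and 164 with only the contrasted arrays. In early KO (0) it was 1 with probes of at least 1 value per group, 2 with every probe and 5 without 0.5 h, and in late KO (1133) 5639 with every probe and 220 without 6 and 8 h, which leaves fewer arrays. In the early response (0) it was 1 under each other filter on missing values, 2 with every probe and 5 without 0.5 h. In the late response (10) it was 0 without centring, with time as a block and without the KO arrays of 6 and 8 h, and 1 with 1 probe per gene. Robust moderation kept each of these counts within that bound. With only the contrasted arrays, equal in number, late KO had 985 genes and late WT had 164. Fewer degrees of freedom alone thus do not explain the late WT count and may not explain the 0 h count. On WT 0 h arrays 370, 314 and 491 genes lay over 2-fold from their own mean, against 149, 174 and 122 on KO 0 h arrays. The main fit uses 1 spread per gene for both genotypes, so p-values that involve WT may be too small. Leaving out 1 array gave 423 to 730 genes at 0 h, 0 to 18 in early WT, 385 to 824 in late WT, 0 to 6 in early KO, 523 to 1100 in late KO, 0 to 5 in the early response and 0 to 6 in the late response. List calls (55) numbered 2 with an estimated correlation and 33 with fry, which does not compare a list with other genes. They numbered 51, 43 and 41 under no centring, quantile normalization and scaling, and 42 to 60 with 1 array left out. These totals can include lists not called in the main fit: of the 55, 28 were kept with fry. Under no centring, quantile normalization and scaling 50, 37 and 35 of the 55 were kept. Values near 0 in late KO changed sign: Hspa1a (-0.01) was 0.061 without centring and -0.088 to 0.11 with 1 array left out, and Dnajb1 (0.00) was -0.24 after quantile normalization, -0.23 after scaling, -0.34 with probes on all arrays, -0.55 with 1 probe per gene, -0.042 with array weights, -0.062 without 6 and 8 h and -0.090 to 0.12 with 1 array left out. With 1 probe per gene, which drops other probes of a gene, Gstm1 turned to -0.13 at 0 h and 0.53 in late KO, Nip7 to 0.014 at 0 h and Bnip3 to 0.34 in late KO, and ribosomal proteins in late WT turned to 0.031 under scaling. Of 246 single-gene results, fewer passed without centring (41 lost), after quantile normalization (46), after scaling (59), with 1 probe per gene (63), and with only the contrasted arrays (111), 75 of 75 were lost with the block and 52 of 97 without the KO arrays of 6 and 8 h, and leaving out single arrays gave 1251 unchanged and 454 lost calls. Signal over background was not examined, so the limit it sets is unknown.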

Other observations

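In this part only the fit without the KO arrays of 6 and 8 h was chosen only after the result was seen. Unstressed KO cells differed from WT cells in further single genes, which were not tested as a group. Penk, which encodes enkephalin precursors, was higher by a log2 of 3.77 ± 0.43 (1 probe, adjusted p = 6.16e-05), the SPARC-related matrix gene Sparcl1 by 2.60 ± 0.23 (adjusted p = 1.11e-05) and Tfpi, an inhibitor of blood clotting, by 2.53 ± 0.26 (adjusted p = 2.25e-05). The growth factor gene Hbegf was lower (-2.23 ± 0.36, adjusted p = 0.00105), as were the chemokine Ccl2 (-1.82 ± 0.39, adjusted p = 0.0079) and the ferritin heavy chain Fth1 (-1.12 ± 0.22, adjusted p = 0.00387), the last of which did not pass with 1 probe per gene. Each of these 6 genes stayed past the threshold with any single array left out. Most genes printed were chosen by that condition, so it is not further support for them. Ccl2 thus started lower in KO cells, and its late rise there, on 4 of 4 arrays (1.42 to 2.14), was measured from that level.

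Some genes fell late in both genotypes. Ccng1, a cyclin induced by p53, fell by 0.81 ± 0.14 in WT and by 1.05 ± 0.14 in KO, the histone variant H3f3b by 1.14 ± 0.19 and 1.29 ± 0.19, and Cks2 by 1.05 ± 0.19 and 1.21 ± 0.19. Irf9 rose in both, by 1.35 ± 0.27 and 1.23 ± 0.27, and its KO call was lost without the KO arrays of 6 and 8 h (1.08, adjusted p = 0.106). Ccng1 passed in neither genotype with 1 probe per gene (-0.68 and -0.56).

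The arrays of each contrast were also split in other ways to ask how often as many genes pass. In late WT cells 1 of 35 splits, the real one, gave 772 genes. In late KO cells 1 of 35 gave 1133 genes. The highest other gave 58 in WT and 359 in KO, and in both it set 4, 6 and 8 h apart from the rest and so followed time. For these 2 results the share of splits as large was under 0.05. The splits treat arrays as exchangeable, and the labels do not say whether the 0 h arrays were separate cultures. A chance difference between cultures is therefore not excluded. Splits for the responses also mix 0 h with later arrays in both genotypes, which breaks the change over time that the genotypes share, so they do not decide on a difference between the responses. For the late response 1 of 100 splits gave 10 genes, and the highest other gave 6, and for the early response 100 of 100 gave at least the 0 genes of the real one, and the highest gave 8. The other 3 contrasts have 10 splits each, too few for a share under 0.05: the real count and the highest other were 705 and 1 at 0 h (1 split as large), 4 and 5 in early WT (2 splits as large) and 0 and 2 in early KO (10 splits as large).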
